A study of Ovis aries with 20 samples.

How the data were processed

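RNA was measured in the jejunum and the ileum, the middle and last parts of the small intestine, of pregnant Hu sheep. The ewes were at 115 days of gestation and had been fed normally or had restricted feed. Total RNA was extracted with Trizol and made into sequencing libraries with an NEBNext Ultra RNA kit, per the labels' protocols. The 20 libraries fall into 4 groups of 5: jejunum under normal feeding, jejunum under restricted feeding, ileum under normal feeding and ileum under restricted feeding. Groups and replicate numbers were taken from the sample titles and the feeding label of each sample. The general treatment note of the labels names restricted feeding even for a sample labelled as normally fed, so it was not used for grouping.

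The authors deposited 1 table per library with a gene ID and an FPKM value, a fragment count scaled by transcript length and library size, per the file headers. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Each jejunal table lists 18058 genes and each ileal one 18051, with 17683 in both. No gene was at 0 in all 10 libraries of a segment. Each of the 18426 IDs is the word gene followed by a number. The files do not pair these IDs with gene names, and 0 of them matched an identifier in the RefSeq gene table for sheep (assembly ARS-UI_Ramb_v3.0). Names were therefore not assigned. The 37 gene lists that were fixed before the data were examined, and the rule for named genes, which needed a symbol, could not be applied. In their place, at most 2 IDs that rose and 2 that fell are printed. In the jejunum they are the gene with the largest increase and the gene with the largest decrease among those that passed and whose groups did not overlap. In the ileum they are the 2 genes that passed. This choice was made after the values were seen.

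FPKM values are not counts, so the main test was limma with a mean-variance trend (version 3.58.1, R version 4.3.3) on log2(FPKM + 1). Genes with at least 1 FPKM in at least 5 libraries of a fit were tested. P-values were adjusted by the Benjamini-Hochberg method over all genes of a fit, and a gene passed at an adjusted p under 0.05. All fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Each comparison used the 10 libraries of its own groups, and the interaction used all 20 with 4 group means. Segment and interaction tests were limited to the 17683 genes listed in both segments. Of the genes listed in the ileum alone, 1 reached 1 FPKM in at least 5 libraries and was left out of these tests, and of those listed in the jejunum alone 0 did. The labels do not say how many ewes gave the samples or that each sample came from a separate ewe, so p-values measure the spread between these samples.

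The total number of reads is unknown. A part of the low FPKM values lay on steps of whole fragments. The depth of each library relative to library 1 of the normally fed jejunum was therefore estimated from the ratios of genes below 0.08 FPKM. Of these ratios, 14.6% to 24.6% lay on the steps in a library, against 1.4% to 2.1% on shifted steps. The estimate differed by at most 0.86% between 2 reference libraries, and by at most 0.55% from the truth in simulated data. All simulated values came from whole fragments, so the error in the real libraries may be larger. Relative depth ranged from 0.903 to 1.27. In the jejunum, restricted library 4 stood at 0.903 and normally fed library 5 at 1.27. Intervals or detection limits that need read counts were not computed.

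Tests were run on simulated data with the spread of the real genes, 200 genes changed and the same number of libraries. The test of feeding in the jejunum, run on 12652 genes, recovered 55% of the genes changed 2-fold and 89% of those changed 4-fold. For the ileum, run on 12830 genes, the shares were 61% and 90%. For the interaction, on 13279 genes, they were 37% and 72%. For the segments they were 68% and 93% under normal feeding (12844 genes) and 40% and 78% under restricted feeding (12640 genes). The sign was right for each recovered gene. Unchanged genes that passed numbered 11 for feeding in the jejunum, 13 in the ileum and 8 for the interaction. For the segments they numbered 5 under normal and 4 under restricted feeding. Noise was drawn independently for each gene and library, with no library standing apart, so these shares need not hold for the real libraries.

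Equal replicate numbers could mark the same ewe in both segments. This was checked by correlating, across 13279 genes, the deviations of a jejunal and an ileal library of equal number from their group means. Under restricted feeding the 5 correlations ran from 0.168 to 0.637, all over the bound of 0.1 set before the data were examined, so these numbers count as pairs by this rule. The pairing comes from the data, since the labels do not state it. Libraries of unequal number also exceeded the bound, at up to 0.445 under restricted and 0.401 under normal feeding. Passing the bound therefore does not by itself mark the same ewe. The main fits, fixed before, have no block, and the blocked value is given beside the segment result under restricted feeding. Under normal feeding the correlations of equal numbers ran from 0.0219 to 0.50 and 4 of 5 were over the bound. These numbers do not count as pairs by this rule, which does not show that they are different ewes.

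The position of each library between jejunum and ileum was computed from 300 genes with the smallest p between the segments under normal feeding, with 1 number left out in turn. A position of 0 is the jejunal mean and 1 is the ileal mean of the normally fed libraries that chose the genes. Normally fed libraries were placed with genes chosen without them, and restricted libraries by their mean over the 5 choices. Differences in a single value per library were tested by exact two-sided permutation unless stated otherwise. Alternatives tried were quantile normalization, rescaling to equal totals, no filter, a filter at 5 FPKM, a pseudocount of 0.1, a single fit of all 20 libraries, a block for the replicate number, a minimum log2 fold change of 1, and each library left out. Library weights had been planned for the interaction. For the other comparisons they were added after the data were seen, as were a random effect for the number and fits without both restricted libraries numbered 2. Relative depth and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.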

Results

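Gene expression was measured by RNA sequencing in the jejunum and ileum of pregnant ewes, to compare the segments' transcriptomes between normal and restricted feeding. Each of the 4 groups held 5 libraries. At 1 FPKM or more, the normally fed jejunum expressed 12661 ± 146 genes (mean ± SD, n = 5) and the restricted jejunum 12432 ± 123. The means differed (exact permutation test, p = 0.0159, adjusted p = 0.0477 over 6 library measures). The groups overlapped, with 12481 to 12851 genes under normal and 12250 to 12593 under restricted feeding. The difference did not reach p under 0.05 at 0.1 FPKM (exact permutation test, p = 0.0714) or at 5 FPKM (exact permutation test, p = 0.0556). In the ileum the counts were 12822 ± 138 under normal and 12609 ± 129 under restricted feeding (exact permutation test, p = 0.0397, adjusted p = 0.0794). Genes above 0 FPKM averaged 16515 in the normally fed and 16303 in the restricted jejunum (exact permutation test, p = 0.0159, adjusted p = 0.0477). In the ileum they averaged 16456 under normal and 16484 under restricted feeding (exact permutation test, p = 0.556, adjusted p = 0.556). Relative depth, on a scale where 1 is the first normally fed jejunal library, was 1.06 ± 0.138 in the normally fed and 0.974 ± 0.043 in the restricted jejunum. In the ileum it was 0.932 ± 0.023 under normal and 1.02 ± 0.048 under restricted feeding. Summed FPKM ranged from 427169 to 518472 per library. The 10 most abundant genes of a library took from 8.9% to 13.4% of it.

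Jejunal and ileal libraries parted along the second principal component of expression. The first principal component held 30.5% of the variance of 13279 genes and the second 25.5%. On the second component the 10 jejunal libraries lay between -28.13 and -8.22. Of the ileal libraries, 8 lay at 3.09 or above, while library 3 of normal feeding lay at -2.28 and library 2 of restricted feeding at -27.44. The jejunal and the ileal library numbered 2 under restricted feeding lay side by side at the far end of the first component, at 49.59 and 54.25. Their expression correlated across genes at r = 0.977.

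**Figure D1:**
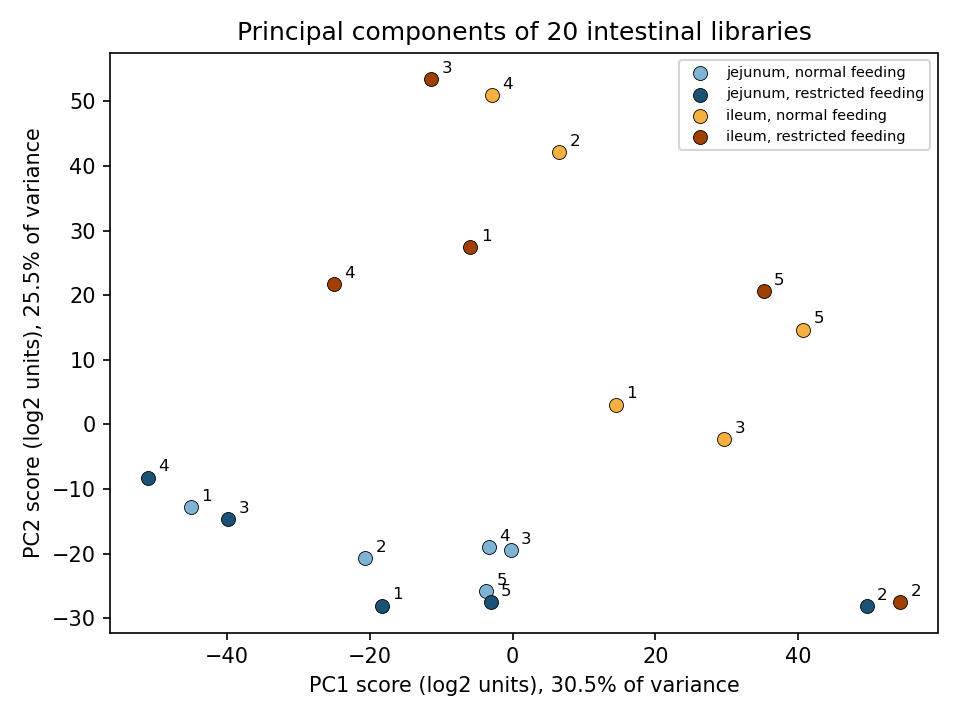
Scores of the 20 libraries on the first principal component (horizontal axis, 30.5% of variance) and the second (vertical axis, 25.5%), in log2 units, with 1 point per library, coloured by group and marked with its replicate number. Ileal libraries lie above jejunal ones, except the restricted ileal library 2, which lies at -27.44 on the second component beside the jejunal library of the same number.

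Restricted feeding was compared with normal feeding in the jejunum first. A group of 58 genes was lower and a group of 11 was higher in the restricted jejunum, so that 84.1% of the 69 genes that passed were lower. The lower genes were mostly of low to moderate abundance. Their median level was 2.77 FPKM under restriction against 7.17 FPKM under normal feeding, 35 of them stayed below 10 FPKM in both groups, and 2 reached 100 FPKM in either. The genes that rose were more abundant, with a median of 55.8 FPKM against 18 FPKM, and 10 of the 11 reached at least 10 FPKM. The median log2 fold change was -1.07 in the lower group and 1.1 in the higher group, and 34 lower and 6 higher genes changed at least 2-fold.

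The largest increase in the jejunum was that of gene13390. It stood at 49.96 ± 32.1 FPKM (SD, n = 5) in restricted and 2.03 ± 2.53 FPKM in normally fed jejunum, a log2 fold change of 4.08 ± 0.623 (SE, limma, adjusted p = 0.0198). The largest decrease was that of gene28839, at 3.21 ± 3.14 FPKM against 16.2 ± 0.926 FPKM (SD, n = 5). Its log2 fold change was -2.30 ± 0.385 (SE, limma, adjusted p = 0.0283). For both genes, all 5 restricted libraries lay on one side of all 5 normally fed ones. Across the alternatives the adjusted p ran from 0.00516 to 0.123 for gene13390 and from 0.00619 to 0.17 for gene28839. Both upper ends came from the block for the replicate number, which joins different ewes here. Apart from it, the highest adjusted p was 0.0723 for gene13390 and 0.1 for gene28839 (limma, without normally fed library 3). The genes passed in 13 and 8 of 19 alternatives.

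In the limma test over 12652 genes, 1068 had an unadjusted p under 0.05 against 633 expected by chance, and 723 of these were lower. All 69 genes had groups that did not overlap, as did 2.66% of all genes tested, against 0.794% by chance. The count rested on single libraries: it was 10, 15, 10 or 11 without normally fed library 2, 3, 4 or 5, and 22 or 42 without restricted library 3 or 4. It was 107 with values rescaled to equal totals, 39 with a filter at 5 FPKM and 156 with library weights, and lower genes outnumbered higher ones in each.

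In the ileum, 2 genes passed. The first, gene20115, stood at 2.13 ± 0.411 FPKM under restricted and 6.09 ± 1.01 FPKM under normal feeding (SD, n = 5), a log2 fold change of -1.18 ± 0.133 (SE, limma, adjusted p = 0.0417). It was also among the genes lower in the jejunum, at 1.18 ± 0.329 FPKM against 4.03 ± 0.551 FPKM, a log2 fold change of -1.21 ± 0.129 (SE, limma, adjusted p = 0.00606). The second, gene17412, stood at 3.2 ± 0.738 FPKM in restricted and 0.784 ± 0.195 FPKM in normally fed ileum (SD, n = 5), a log2 fold change of 1.22 ± 0.15 (SE, limma, adjusted p = 0.0446). In the jejunum its log2 fold change was 0.86 ± 0.267 and did not pass (limma, adjusted p = 0.287), and restricted library 1 lay at 0.711 FPKM, below all 5 normally fed libraries. Across the alternatives the adjusted p ran from 3e-04 to 0.166 for gene20115 and from 0.0106 to 0.199 for gene17412. The 0.166 came from the block for the replicate number, and the next highest was 0.164 (limma, without normally fed library 1).

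**Figure D2:**
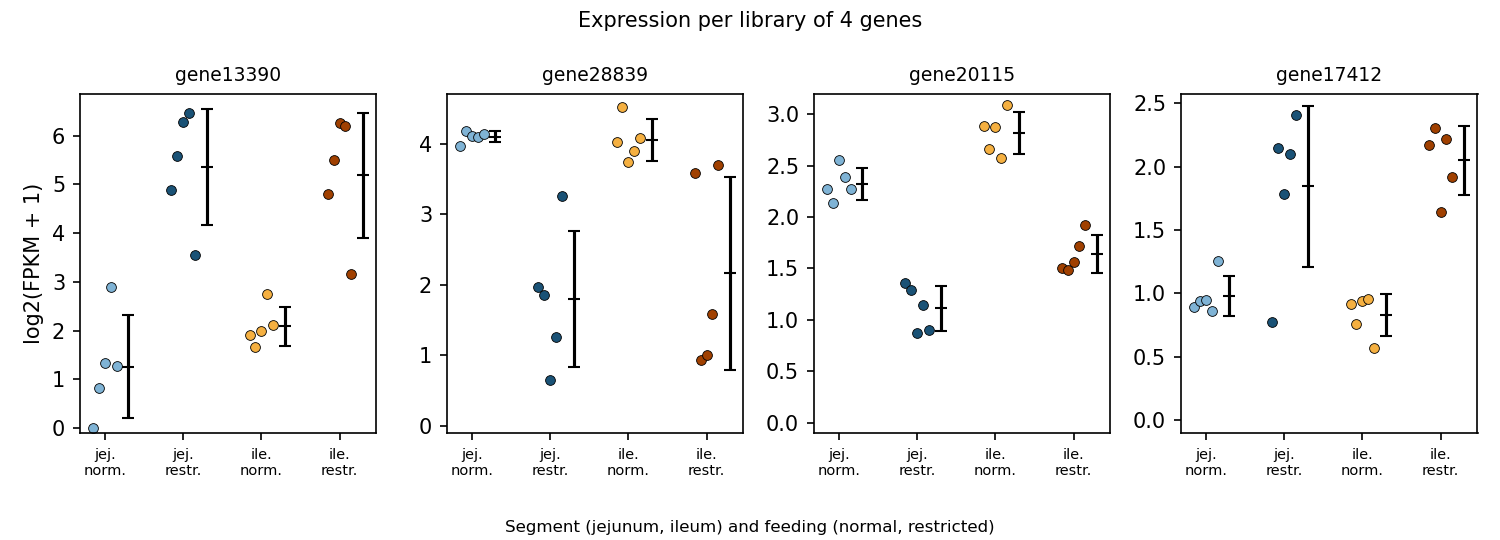
Expression of the 4 genes in each library as log2(FPKM + 1) on the vertical axes, which differ between panels, with groups by segment and feeding on the horizontal axes. Points are libraries and bars are the mean and SD of 5. For gene17412, 4 restricted jejunal libraries lie above the normally fed ones and library 1, at 0.711 FPKM, lies below them. The restricted libraries of gene13390 lie above, and those of gene28839 and gene20115 below, all normally fed libraries of the same segment.

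Over 12830 ileal genes, 1165 had an unadjusted p under 0.05 in the limma test against 642 expected, 884 of them lower. The count of 2 was unstable: it was 73 in a single fit of all 20 libraries, 8 with library weights, 7 or 5 without restricted library 5 or 3, 1 without restricted library 2, and 0 without any other library. It was also 0 with no filter or a filter at 5 FPKM. Neither of the 2 genes met the filter at 5 FPKM, and gene17412 missed the main filter in each fit without a restricted library. Of the 2 genes, gene20115 alone passed without restricted library 5 or 3, and neither passed without restricted library 2.

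The genes that passed in the jejunum were then followed in the ileum. Of the 58 lower genes, 57 were also lower in the restricted ileum, with a median log2 difference of -0.815. All 11 higher genes were also higher there, with a median of 1.24. In all, 54 of the 69 had the same sign with an unadjusted limma p under 0.05 in the ileum, and 53 passed when p-values were adjusted over these 69 genes. The mean ileal difference in the jejunal direction was 0.894 on the log2 scale. It was the highest of the 252 labellings of the ileal libraries (exact one-sided permutation test, p = 0.00397, the smallest this test can give). An average of 94.5% ± 3.14 of these genes moved in the jejunal direction in a restricted ileal library (SD, n = 5). If equal numbers mark the same ewe, these ileal values are not independent of the jejunal ones.

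**Figure D3:**
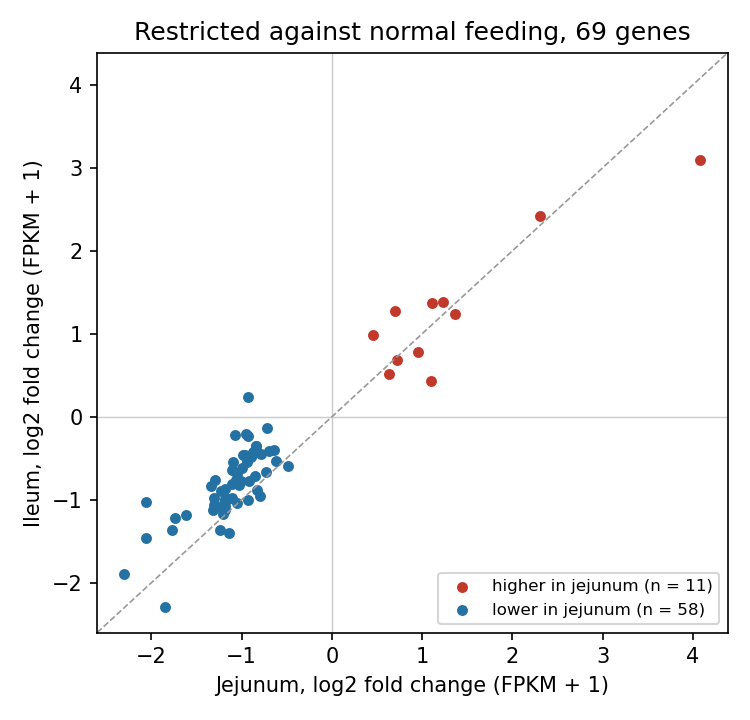
Log2 fold change (FPKM + 1) of restricted against normal feeding in jejunum (horizontal axis) and ileum (vertical axis) for the 69 genes that passed in the jejunum, with 1 point per gene and a dashed line of equal change. The 11 higher and 57 of the 58 lower genes have the same sign in the ileum.

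Whether feeding acted differently in the segments was tested by the interaction. No gene had a feeding difference that passed between jejunum and ileum (limma, 13279 genes, smallest adjusted p = 1). At an unadjusted p under 0.05 there were 262 genes against 664 expected. Among the 69 jejunal genes, 8 had an unadjusted interaction p under 0.05. The ileal change was smaller than, or opposite to, the jejunal one in 57 of them, with a median shortfall given by an interaction estimate of -0.242 in the jejunal direction. These genes were chosen for their jejunal change, which favours such a shortfall. With a random effect for the replicate number 624 genes, with a replicate block 546 and with library weights 511 had an unadjusted p under 0.05, and 0 passed in each. The genes that passed in the jejunum and not in the ileum are therefore not shown to differ between segments.

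Jejunum and ileum were compared under normal feeding. A group of 552 genes was higher in the ileum and a group of 276 was higher in the jejunum. The genes higher in the ileum had a median log2 fold change of 0.68, and 142 of them differed at least 2-fold, 43 at least 4-fold and 10 at least 16-fold. Those higher in the jejunum had a median of -0.965, with 132, 54 and 8 genes at these sizes. Among the genes higher in the ileum 54 reached 100 FPKM, as did 47 of those higher in the jejunum. A small group was nearly silent in one segment, below a mean of 1 FPKM, and at 10 FPKM or more in the other. It held 9 ileal genes, with a median of 35.4 FPKM in the ileum and 0.0799 FPKM in the jejunum, and 8 jejunal genes, with 17.5 FPKM in the jejunum and 0.218 FPKM in the ileum.

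The most ileal gene by fold change stood at 4979 ± 3360 FPKM in the ileum and 2.04 ± 1.67 FPKM in the jejunum (SD, n = 5), a log2 fold change of 10.53 ± 0.547 (SE, limma, adjusted p = 6.66e-06). The most jejunal gene stood at 4161 ± 2180 FPKM in the jejunum and 24.1 ± 44.5 FPKM in the ileum, a log2 fold change of -9.08 ± 1.02 (SE, limma, adjusted p = 0.000729). Both passed in all 19 alternatives. Of 12844 genes, 2658 had an unadjusted p under 0.05 in the limma test against 642 expected, and the groups of 740 of the 828 genes did not overlap, as against 8.82% of all genes and 0.794% by chance. The direction of the calls depended on the scaling: 400 genes were higher in the ileum and 377 in the jejunum after quantile normalization. The count was 386 in a single fit of all 20 libraries, 394 or 498 without jejunal library 2 or 5, and 485 without ileal library 2.

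Under restricted feeding the same comparison gave 0 genes that passed (limma, 12640 genes, smallest adjusted p = 0.147). At an unadjusted p under 0.05 there were 1397 genes against 632 expected, 1026 of them higher in the ileum. With the number as a block, 0 genes passed and 2614 had an unadjusted p under 0.05. The genes that set the segments apart under normal feeding nevertheless kept their direction: 542 of the 552 ileal and 269 of the 276 jejunal genes had the same sign. Their median log2 difference was 0.592 in that direction, against 0.75 under normal feeding, or 0.721 without number 2, and 429 of the 828 had the same sign with an unadjusted p under 0.05. The 9 ileal genes that were nearly silent in the normally fed jejunum had a median of 42.9 FPKM in the restricted ileum and 1.25 FPKM in the restricted jejunum, and 5 of them reached a mean of 1 FPKM there. Library 2 carried this level: without it the jejunal median was 0.249 FPKM and 2 of the 9 genes reached a mean of 1 FPKM. The 8 jejunal genes had a median of 18.6 FPKM in the jejunum and 0.25 FPKM in the ileum.

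The libraries numbered 2 stood apart in this comparison. On the axis from jejunum (0) to ileum (1), the jejunal library 2 lay at 0.644, where the next highest jejunal library lay at 0.181. The ileal library 2 lay at 0.665, within the range of the ileal libraries, of which restricted library 4 was lower at 0.55. The distance between both was 0.0203. Both held little of the genes nearly restricted to a segment. The 9 ileal genes had a median of 2 FPKM in the jejunal and 2.89 FPKM in the ileal library 2, against 20.5 to 72.7 FPKM in the other restricted ileal libraries. The 8 jejunal genes had a median of 0.425 FPKM and 0.281 FPKM, against 10 to 20.7 FPKM in the other restricted jejunal libraries. For the restricted numbers 1, 3, 4 and 5 the distances were 0.963, 1.09, 0.693 and 0.983. For normally fed numbers the mean distance was 0.934 ± 0.191 (SD, n = 5), and for all restricted numbers it was 0.75 ± 0.433 (exact permutation test, p = 0.516). Of the 828 segment genes, 56.3% had the sign of normal feeding in number 2, against 85% to 96.1% in the other restricted numbers. Without both libraries numbered 2, 815 genes passed with the number as a block and 244 without a block, the latter 166 higher in the ileum and 78 higher in the jejunum, and 153 of the 244 were among the 828, where independent lists would share 16.2. The count was 129 without the jejunal and 96 without the ileal library 2 alone, 307 in a single fit of all 20 libraries and 477 with library weights.

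**Figure D4:**
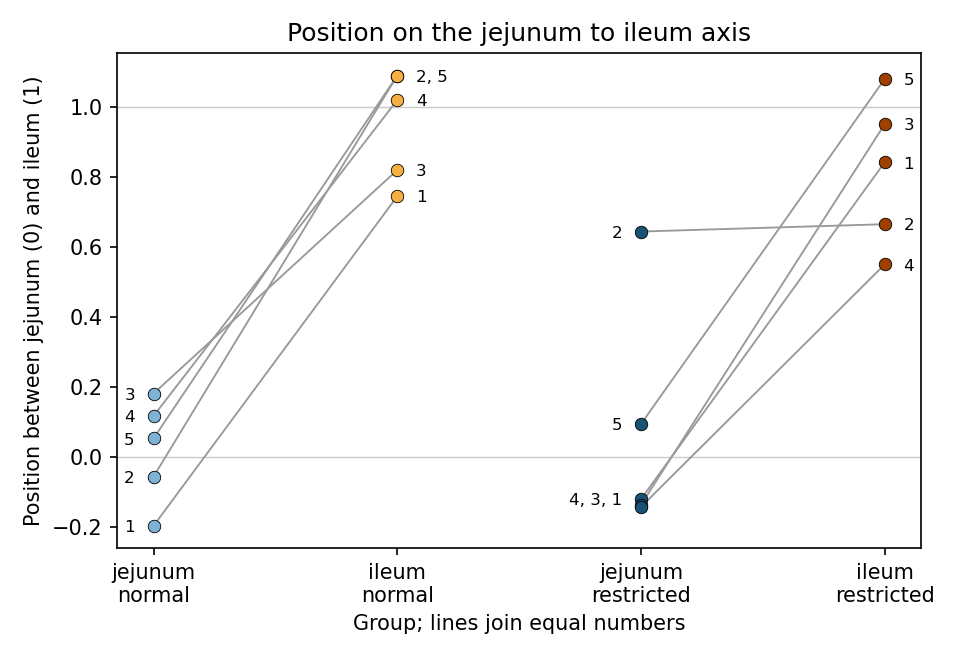
Position of each library between the normally fed jejunal mean (0) and ileal mean (1) on the vertical axis, by group on the horizontal axis, with lines joining libraries of equal number. Lines climb by 0.639 to 1.15 except that of restricted number 2, which stays at 0.644 and 0.665.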

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

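The tests of a shift of all genes and of jejunal library 2 for the direction of the jejunal changes, of the pair numbered 2, of the segment distance over all 5 numbers and of the jejunal genes in ileal library 2 were chosen only after the result was seen. All fits without both libraries numbered 2, the library weights (except for the interaction, where they were planned), the average over both segments and the sorting of splits by the libraries numbered 2 were also chosen after seeing the data, and the test of the distance without number 2 was set once this number had been seen to stand apart.

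No gene passed between the segments under restricted feeding, against 828 under normal feeding, but a single fit of all 20 libraries gave 307 against 386 and no gene passed the interaction, so a difference between the feeding groups is not shown. Lower depth is argued against by a median relative depth of the restricted libraries 1.04 times that of the normally fed ones, while a narrower gradient stays open: the mean jejunum to ileum distance was 0.803 of the normally fed mean over all 5 restricted numbers (exact permutation test, p = 0.516), and the 0.998 over numbers 1, 3, 4 and 5 decides nothing, since number 2, with the smallest distance, was left out. Without both libraries numbered 2, 244 genes passed, 54.1% of the median of 451 that normal feeding gave with 1 number left out (range 181 to 496). With the number as a block 815 passed, 183% of a median of 445 (range 142 to 715), but the normally fed numbers did not count as pairs. Number 2 was left out for its small distance, which favours a higher count. These counts therefore do not decide whether the pair numbered 2 explains the 0, and this pair stays a candidate explanation. Whether its ileal library is jejunum cannot be told: the 8 genes nearly restricted to jejunum had a median of 0.281 FPKM in it, against 9.07 FPKM or more in each normally fed jejunal library, but the jejunal library of this number held only 0.425 FPKM and was its closest match, at r = 0.977 against at most 0.949 for ileal libraries. The jejunal library 2 is no clearer. Apart from its pair, it correlated at 0.860 to 0.957 with ileal and at 0.860 to 0.933 with jejunal libraries. The 9 genes nearly restricted to ileum had a median of 2 FPKM in it, against 10.6 FPKM or more in each normally fed ileal library. Whether it is ileum cannot be told either. An exchange of both libraries numbered 2 would leave their distance as small. Tissue from another site, a sample from outside the groups and the ewe itself stay open and untested.

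More genes were lower than higher in the restricted jejunum. A shift of all genes by the authors' scaling would move the median, which was -0.00854, and 78% of the calls were still lower after quantile normalization. Lower depth is argued against by a ratio of median relative depths of 0.981, though the means were 0.974 in restricted and 1.06 in normally fed jejunum. Library 2 alone is argued against by 59 lower genes without it. That restricted feeding itself lowers more genes than it raises may remain as a hypothesis, found and tested on the same libraries; differences between the ewes other than feeding were not tested.

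Feeding differences in the jejunum and the ileum went together, with r = 0.617 across 12471 genes, which are not independent replicates. When the 10 numbers were split in all possible ways in both segments at once, 24 of the 126 splits, the real one included, gave a correlation as high, and the highest other split gave 0.822. The overall agreement may thus come from ewes that gave both samples, and it does not by itself show a feeding effect in both segments. With the jejunal groups kept and the ileal libraries alone split, the real grouping gave the highest absolute correlation of 126, against a median of 0.189 for the others. A feeding effect shared by the segments stays open, since shared ewes would also raise this value.

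Whether other groupings would give as much was checked by refitting other splits of the same libraries. For feeding in the jejunum, 1 of 100 splits, the real one, gave 69 genes or more, and the highest other split gave 3. For the segments under normal feeding, 1 of 100 gave 828 or more, and the highest other gave 2. This share was under 0.05 for both, so a random split of these libraries rarely gives such counts. It cannot tell feeding or segment from other differences between the groups of samples. For feeding in the ileum, 2 of 100 splits gave 2 genes or more, the real one included, a share under 0.05, but the other one gave 40, which points to a structure of the ileal libraries. It set normally fed libraries 1 and 3 and restricted libraries 1, 2 and 4, at 0.55 to 0.842 on the axis from jejunum to ileum, against the rest, at 0.951 to 1.09, so this structure follows the position on that axis. For the interaction, 26 of 100 splits gave as many genes with an unadjusted p under 0.05 as the real 262, the highest 966, so chance cannot be excluded. Under restricted feeding the segments were exchanged within numbers: the real grouping gave 1397 genes with an unadjusted p under 0.05 and the highest of the others 1213, the real one being 1 of 16 splits, too few for a share under 0.05. The exchange was not the test fixed beforehand, which took splits that need not part the pairs. In that test 16 of 100 splits, the real one included, gave 1397 or more, so chance cannot be excluded. Of these 100 splits, the 46 with both libraries numbered 2 on one side had a median of 817 such genes and reached 4373. In these 46, 15 gave 1397 or more. The 54 that parted these libraries had a median of 228, and only the real one gave 1397.

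Single libraries lay far from the other 4 of their group in 7 of 70 sets of 5 values. About 3.5 would be expected of independent values with a normal distribution. FPKM values need not follow it, and the sets share libraries, so 3.5 is only a rough guide. Library 1 of the normally fed jejunum correlated with the mean of its group at 0.965, against 0.982 to 0.987 for the others. For gene13390, normally fed jejunal library 4 stood at 6.42 FPKM, against 0 to 1.53 in the others. For gene17412, normally fed jejunal library 5 stood at 1.38 FPKM, against 0.821 to 0.925. Restricted jejunal library 2 held 29.8 FPKM of the most ileal gene, against at most 8.64 in the others of its group, and 6.32 FPKM of the second most ileal gene, against at most 0.802. Its level of the most jejunal gene was 149.9 FPKM, against 4484 to 10434 FPKM in the other restricted jejunal libraries. Restricted ileal library 2 held 2.78 FPKM of the most ileal gene, against 799 to 7937 FPKM in the other restricted ileal libraries. Neither of these values is among the 7, since the other libraries of each group also spread widely. The most jejunal gene stood at 103 FPKM in normally fed ileal library 1, against at most 13 in the others, and at 467 FPKM in restricted ileal library 4, against at most 49.6.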

How the results depend on the processing

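Both shares of genes with the same sign, library weights (planned for the interaction only), fits without both libraries numbered 2 and a random effect for the number were chosen after seeing the data. The cause of each shift below was not tested, except that a stricter filter or a minimum fold leaves fewer genes and a left-out library fewer samples. Feeding in the jejunum gave 69 genes, and 107 with equal totals, 39 with the filter at 5 FPKM, 40 at a log2 fold change of 1 or more, 156 with library weights and 10 to 99 with 1 library left out. Feeding in the ileum gave 2 genes, and 0 with no filter or the filter at 5 FPKM, 1 with a pseudocount of 0.1, 73 in a single fit of all 20 libraries, 8 with library weights and 0 to 7 with 1 library left out. The segments under normal feeding gave 828 genes, and 386 in a single fit, 274 at a log2 fold change of 1 or more and 394 to 774 with 1 library left out. Under restricted feeding they gave 0 genes, and 1 with no filter, 307 in a single fit, 477 with library weights, 0 to 129 with 1 library left out, 244 without both libraries numbered 2 and 815 with a replicate block as well. The interaction gave 0 genes in every alternative run, 0 to 0 with 1 library left out. The share of segment genes with the same sign in restricted numbers was 83.2% to 93.2%, the highest without number 2, and that of jejunal feeding genes in restricted ileal libraries 91.9% to 98%, with 1 library left out.

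With the replicate number as a block, 0 genes passed for feeding in the jejunum and 0 in the ileum, where equal numbers are different ewes (3 of 10 same-number correlations over 0.1), 806 for the segments under normal feeding, 0 under restricted feeding and 0 for the interaction; under normal feeding 3 of 5 jejunal libraries matched their own number best, and under restricted feeding 5 of 5. None of the 8 genes whose values were followed singly changed sign in an alternative: gene13390 passed in 13 of 19 alternatives, gene28839 in 8 of 19, gene20115 in 8 of 18 and gene17412 in 5 of 13. Alternatives in which a gene missed the filter are not counted. These were the filter at 5 FPKM for gene20115 and gene17412, and each fit without a restricted ileal library for gene17412. The deficit of genes at 1 FPKM or more in the restricted jejunum kept an exact permutation p under 0.05 in 10 of 10 fits without 1 library, but not at 0.1 or 5 FPKM, and that in the ileum in 4 of 10. Gene list tests, with their estimated correlation, fry, block and left-out libraries, were not run, since no ID has a name. Read depth is known only relative to other libraries, so limits for genes at 0 cannot be set.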

Other observations

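The average over both segments, the count of extreme genes per number and the comparison of spread were chosen after seeing the data.

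When the jejunal and ileal log2 values of each number were averaged, 91 of 13279 genes differed between 5 restricted and 5 normally fed numbers (limma, adjusted p under 0.05), 74 lower and 17 higher under restriction. Of these, 51 had also passed in the jejunum alone. The real grouping was 1 of 100 splits with as many genes, and the highest other split gave 2. That share is under 0.05, but the average was chosen after seeing the data. The averaging assumes that equal numbers mark the same ewe, which the rule for pairs did not give under normal feeding. The count fell to 20, 23, 23 or 4 without normally fed number 2, 3, 4 or 5 and to 50 or 22 without restricted number 3 or 4, was 193 without restricted number 5, and was 91 without restricted number 2.

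The level of gene13390 varied more between restricted numbers than between the segments of a number. In the order of numbers 1 to 5 it stood at 28.4, 47, 76.6, 87.2 and 10.7 FPKM in the jejunum and at 26.9, 44.3, 75.8, 72.7 and 7.92 FPKM in the ileum. For gene28839 the numbers were less alike: restricted number 1 stood at 2.93 FPKM in the jejunum and 11 FPKM in the ileum.

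The restricted libraries numbered 2 differed from all others over many genes. In 9.67% of 13279 genes both lay above all other libraries, and in 8.99% both lay below, where chance gives 0.526%. The next highest shares were 1.5% above and 2.36% below, for restricted number 4. In 3 genes both lay above the highest other library by at least 2-fold on the log2(FPKM + 1) scale.

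The spread within groups was also compared. The median SD of log2 values was 0.278 in the restricted and 0.185 in the normally fed jejunum, and 0.304 and 0.231 in the ileum. The correlation of a library with the mean of the others in its group was lower under restriction in both segments, by a margin that did not pass (exact permutation test, p = 0.0794 in each). Without library 2 the restricted SDs were 0.223 and 0.264.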
